A study of Mus musculus with 3 samples.

How the data were processed

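The series holds 3 single-cell RNA libraries of sorted retinal microglia from Balb/c mice, 1 library per group. The groups were uninfected and untreated mice (control), mice infected at birth with murine cytomegalovirus (MCMV, a mouse herpesvirus) and left untreated (infected), and infected mice given PLX5622. PLX5622 is an inhibitor of CSF1R, the receptor whose signal microglia need to survive, so that feeding it removes most of them and stopping it lets them grow back. Each library pooled 5 mice aged 6 months. Per the labels' protocols, pups received 200 PFU of strain K181 within a day of birth or a PBS injection, and the treated group ate PLX5622 chow for 7 days from the age of 2 months. The series' design text gives 21 days for repopulation. These periods end well before the age of 6 months, so the full time of regrowth before sampling is unclear. Cells were sorted as CD45 intermediate and CD11b positive, and libraries were made with the 10x Genomics 3' v3.1 chemistry. The sample labels name retina as the tissue, while the design text names retina and RPE/choroid (the pigment epithelium and the vascular layer behind it). Groups were taken from the sample titles.

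The authors deposited filtered matrices of raw UMI counts per feature and barcode, a UMI being 1 captured RNA molecule. Per the submitters' processing notes these come from Cell Ranger and the mm10 genome build; the Cell Ranger version and settings and the gene annotation are not given in the sources used here. Each matrix held 33696 gene features and 14 antibody tag features; the tags are not described in the labels. Gene IDs of 31961 features were found in GENCODE vM21 (GRCm38, the assembly also called mm10), from which coordinates were taken. The deposited matrices held 6995 barcodes and 39463397 gene UMIs for the control, 5998 barcodes and 36543965 gene UMIs for the infected library, and 7000 barcodes and 19642727 gene UMIs for the PLX5622 library. The lower UMI total of the last one widens its counting intervals.

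Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Under 500 genes were found in 41.7% of control, 43.2% of infected and 57.3% of PLX5622 barcodes, and over 10% mitochondrial UMIs in 30.4%, 34.3% and 39.1%. Scrublet, run per library as implemented in scanpy 1.11.5, called 33 of 3725, 21 of 3140 and 13 of 2849 passing barcodes doublets. These rates of 0.886%, 0.669% and 0.456% are low for libraries of this size, so some doublets may have been missed. After their removal 3692, 3119 and 2836 cells were kept, with median UMI counts of 7215, 7454 and 4242. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were scaled (limit 10) and reduced to 30 principal components, cells were joined to 15 nearest neighbours, and the shared-neighbour graph was clustered by the Leiden method at resolution 1 with seed 1 and no batch correction. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.

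The 27 clusters were named from 20 fixed marker lists. A marker counted for a cluster at 50 CPM or more and 1.5 times the mean over all clusters. A name needed at least 3 such markers and a share of at least 0.333 of the class's measured markers. It was withheld where several classes within a share of 0.1 had markers among the cluster's 10 leading genes, or where another class led there. Clusters of low depth without a leading marker would also have been left unnamed. In this way 24 clusters were named. The microglia-like class joined 8 clusters, the macrophage-like class (perivascular or choroidal macrophage markers) 2 clusters and the RPE-like class (retinal pigment epithelium or melanocyte markers) 5 clusters. The thresholds on markers were set after the data were seen and left clusters 11, 12 and 21 unnamed. Cluster 11 held 5.31%, 3.72% and 2.72% of kept control, infected and PLX5622 cells, cluster 12 held 5.28%, 3.82% and 0.917%, and cluster 21 held 0.623%, 0.192% and 1.34%.

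With 1 library per group there is no replicate check of any difference, no test was made, and every value describes these libraries. UMIs were summed over the cells of a class and given as CPM, the count scaled to a common total of all UMIs in those cells. The sums over microglia-like cells were 23291725, 23616184 and 7605540 UMIs. Ratios of CPM carry an exact conditional binomial 95% interval, and shares of cells an exact Clopper-Pearson 95% interval; all intervals cover counting error only. A count of 0 was taken as a limit of 3 counts. Scaling to all UMIs left the median gene at a log2 ratio of 0.06 for infected against control, 0.08 for PLX5622 against infected and 0.11 for PLX5622 against control, over 3662, 3864 and 3848 genes with 50 CPM or more. Ratios are printed without taking this shift out.

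The comparisons, cell filter, gene lists, markers and rule for named genes were fixed before the data were examined. Per comparison, among genes with at least 50 CPM in the higher library (leaving out mitochondrial, ribosomal protein, predicted, haemoglobin, immunoglobulin and T cell receptor genes), the 12 highest and the 12 lowest ratios could be named. Up to 4 members with the largest change in each list at 20 CPM or more could be named too, and P2ry12, Tmem119, Csf1r, Apoe, H2-Aa, Cd74 and B2m were taken in each comparison; some genes that the rule takes are not reported here. Other genes named in the text were chosen after their values were seen. The 19 lists covered homeostatic microglia, disease-associated microglia, type I interferon response, interferon gamma response, MHC class I presentation, MHC class II presentation, inflammatory cytokines and NF-kB, complement, phagocytosis and lysosome, lipid and cholesterol metabolism, angiogenesis and growth factors, glycolysis and hypoxia, oxidative phosphorylation, proliferation, CSF1R with TGF-beta and growth factor signalling, a signature of macrophage-derived microglia-like cells, immediate early and dissociation genes, unfolded protein and oxidative stress, and senescence and ageing. Of their members 652 were matched by symbol, 7 by gene ID and 3 were not matched. A member counted as higher or lower at a ratio of 1.5 or more in either direction. The percentile of a list's median among 10000 random lists, of the same size and matched on mean expression in 20 bins, is a description of these libraries. The interval of a median came from 1000 resamplings of members and counts.

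Shares of cells with a UMI were computed after thinning each cell to 1500 UMIs, which left out 1.96%, 1.09% and 5.56% of microglia-like cells. The ratio step was tested on simulated counts, in which all changed genes of 1.5-fold, 2-fold and 4-fold came back within 0.25 log2. Intervals covered the simulated ratio for 95.1% of 3503 genes in the infected against control simulation, 95.4% of 3607 genes for PLX5622 against infected and 95.0% of 3558 genes for PLX5622 against control. Of 95 unchanged lists per comparison 2.11% fell outside the central 95%. The simulated counts followed the Poisson model that the intervals assume, without spread between cells or libraries. They check the calculation and not the real spread.

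Alternatives fixed in advance were all barcodes without a filter, a stricter filter (1000 genes, 5% mitochondrial UMIs), doublets kept, Leiden resolutions 0.5 and 2, each library clustered on its own, median-ratio scaling, a total without mitochondrial and ribosomal protein genes, all kept cells, microglia-like and macrophage-like cells together, the mean of per-cell CPM, thinned cells, and list members at any count or at 50 CPM. Others were chosen after seeing the data: unnamed clusters 11 and 12 added, cluster 9 left out, only microglia-like clusters low in immediate early genes (1, 9, 14 and 19), resolution 0.5 or 2 and kept doublets for expression values, infected cells in swapped parts, the macrophage-like and RPE-like classes, and the antibody tags. Tag counts were divided by the IgG2a isotype tag of the same cell, with 1 added to both, and the median over cells was taken.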

Results

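Gene expression was measured in single cells sorted from the eyes of 6-month-old Balb/c mice, in 3 libraries of 5 pooled mice each. The libraries came from uninfected control mice, from mice infected with MCMV at birth, and from infected mice that had eaten PLX5622 chow, stopped, and let their microglia grow back. The deposited counts hold 39463397 gene UMIs for the control, 36543965 for the infected and 19642727 for the PLX5622 library. Kept cells numbered 3692, 3119 and 2836. Since there was 1 library per group, animal, pool and library differences cannot be separated from the group.

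Microglia, the resident macrophages of the retina, made up the largest named class in the control and infected libraries. In the PLX5622 library they and RPE-like cells held similar shares, and with all barcodes counted the order turned (13.7% against 22.6%). Microglia-like clusters, carrying markers such as P2ry12 and Tmem119, held 1739 control cells (47.1% of kept cells, exact 95% interval 45.5 to 48.7%), 1555 infected cells (49.9%, 48.1 to 51.6%) and 1080 PLX5622 cells (38.1%, 36.3 to 39.9%). RPE-like cells, with markers of the pigment epithelium or melanocytes, held 31.1%, 33.8% and 36.5%. They passed the CD45 intermediate, CD11b positive gate although neither protein is expected on them, so shares of kept cells describe what passed the gate and the filter. Macrophage-like clusters (8 and 15), with markers of perivascular and choroidal macrophages such as Mrc1 and Pf4, held 181 control cells (4.90%, 4.23 to 5.65%), 118 infected cells (3.78%, 3.14 to 4.51%) and 370 PLX5622 cells (13.05%, 11.8 to 14.3%). The last order turned when each library was clustered on its own, which gave 6.28% in the infected and 1.73% in the PLX5622 library, since 205 of the 370 cells then fell in an unnamed cluster led by Cxcl2, Mmp13 and Mmp12 with Mrc1 among its top genes. A further 79 fell in an unnamed cluster led by Nrxn3 and Pcp2, genes of retinal bipolar neurons. Macrophage-like cells also carried P2ry12, at 717, 892 and 749 CPM (control, infected, PLX5622) beside 1233, 1361 and 1255 CPM in microglia-like cells. Of 14 macrophage markers cluster 8 raised 5 and cluster 15 raised 8, and Lyve1 and Cd163 stood under 20 CPM in the class. The class may thus hold microglia too.

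Rarer classes included neutrophils, at 2.14%, 1.28% and 0.423% of control, infected and PLX5622 cells, and monocytes, at 1.46%, 1.28% and 0.917%. Rod photoreceptors held 1.16%, 1.15% and 3.103%, NK cells 0.542%, 0.545% and 0.705%, and plasma cells 0.325%, 0.609% and 0.423%. The cluster named mural cell or fibroblast-like held 0.987% of PLX5622 cells and none of the control and infected cells. Unnamed cluster 21, with both endothelial and mural markers, held 0.623%, 0.192% and 1.34% of control, infected and PLX5622 cells. Mast cells or basophils held 0.846% of PLX5622 cells and 1 control cell, and no infected cell. The median depth of microglia-like cells was 10582, 10062 and 5599 UMIs, so the PLX5622 library was the shallowest.

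**Figure D1:**
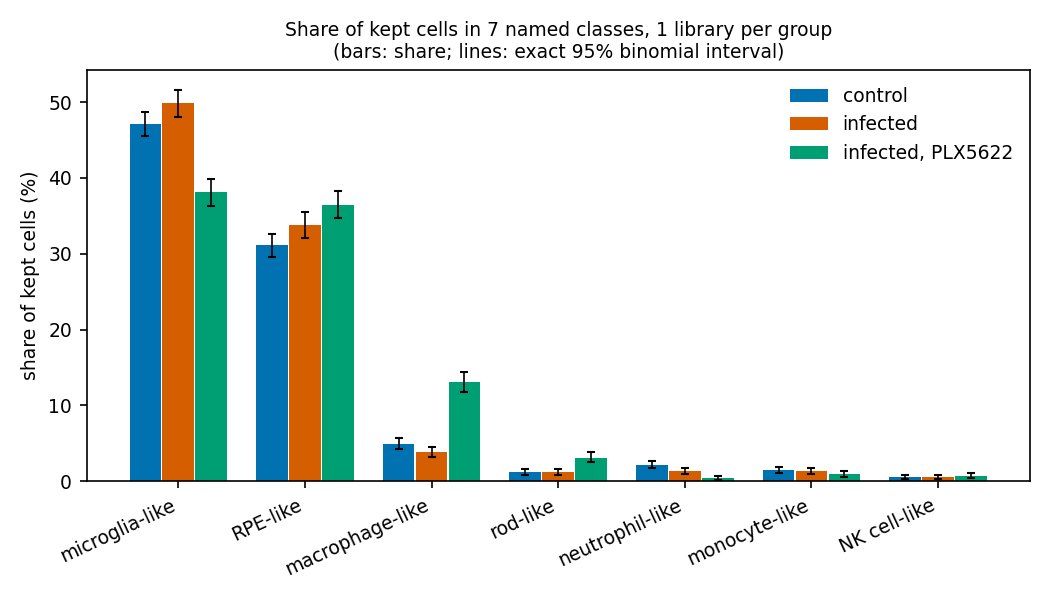
Percent of kept cells (vertical axis) in 7 named cell classes for the control, infected and PLX5622 libraries, with exact 95% binomial intervals as error bars. Microglia-like cells held 47.1%, 49.9% and 38.1%, and macrophage-like cells 4.90%, 3.78% and 13.05%.

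The first comparison, infected against control, asks what infection at birth left behind in adult retinal microglia. Antigen presentation and interferon genes were higher in infected microglia-like cells. H2-Aa, a chain of the MHC class II molecule that shows peptides to CD4 T cells, was at 178 CPM against 21.0 CPM in the control, a ratio of 8.47 (95% interval 7.71 to 9.32). Cd74, the class II chaperone, was at 805 against 155 CPM, a ratio of 5.19 (5.01 to 5.38). H2-K1, an MHC class I heavy chain, was at 2.39 times the control level (2.33 to 2.44). The T cell attracting chemokine Cxcl9 had no count in the control and stood at 26.2 CPM in infected cells, at least 203-fold higher against a limit of 3 counts. Among infected microglia-like cells clusters 4, 1, 5 and 6 held 26.3%, 23.3%, 17.2% and 16.1%, and among control cells clusters 6, 5, 4, 9 and 1 held 21.0%, 18.8%, 18.1%, 17.4% and 16.2%.

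Of the 12 measured members of the MHC class II list, 5 were at least 1.5 times higher in infected cells and none lower, with a median log2 ratio of 0.27 (interval 0.05 to 2.15) at percentile 99.98 of random lists. Besides H2-Aa and Cd74 these were H2-Eb1 (9.71 times), H2-DMb1 (3.53 times), which loads peptide, and H2-Ab1 (3.26 times). H2-Ea, outside the list, stood at 9.004 times the control level. Cells with 10 or more class II UMIs made up 110 of 1739 control and 475 of 1555 infected microglia-like cells and held 53.1% and 91.1% of these UMIs. The other cells averaged 1.89 and 2.80 class II UMIs. After thinning each cell to 1500 UMIs, H2-Aa gave a UMI in 1.17% of control and 11.8% of infected microglia-like cells, against 0.390% and 0.661% of RPE-like cells, which should lack it. Without thinning these shares were 4.49%, 30.1%, 0.783% and 1.42%, at median depths of 10582 and 10062 UMIs in microglia-like and 3030 and 2894 in RPE-like cells. The macrophage markers Mrc1 and Pf4 stood at 5.41 and 4.98 CPM in control and 3.77 and 5.08 CPM in infected microglia-like cells.

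The MHC class I list had 12 of 22 members at least 1.5 times higher and none lower, with a median of 0.60 (0.30 to 0.90) at percentile 100. Nlrc5, the transactivator of class I genes, was at 3.15 times the control level, H2-Q6 and H2-Q7 at 2.74 and 2.67 times, and B2m, the shared light chain, at 1.33 times. H2-Q6 and H2-Q7 are near copies of each other, so the split of counts between them is uncertain. The type I interferon list, genes that cells switch on against viruses, had 13 of 27 members higher and none lower (median 0.57, 0.37 to 0.68, percentile 100). Its examples were Ifi204 (2.84 times), Ifit2 (2.21 times) and Sp100 (1.92 times). The interferon gamma list had 7 of 21 members higher and none lower (median 0.33, 0.14 to 0.77, percentile 100). The GTPases Iigp1, at 25.6 against 0.644 CPM, and Gm4951, at 46.2 against 6.65 CPM, reached 39.7 (23.9 to 71.4) and 6.94 times the control level. Cxcl13, a B cell attracting chemokine, stood at 55.4 against 4.21 CPM, a ratio of 13.2 (10.7 to 16.3). Cluster 13, marked by Cxcl13, Cxcl9 and Iigp1 among others, held 20 of 1739 control, 107 of 1555 infected and 54 of 1080 PLX5622 microglia-like cells. In the complement list C4b was the single member of 10 past 1.5 times, at 11.97 times the control level (9.67 to 14.98), with a list median of 0.00.

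Genes of dividing cells were lower in infected microglia-like cells. The proliferation list had 7 of 10 members lower and none higher (median -1.01, -2.00 to -0.47, percentile 0), with Mki67 at 0.242, Top2a at 0.2504 and Cenpf at 0.209 times the control level. Stmn1, which loosens microtubules, was at 0.266 times. Cluster 19, marked by Top2a, Mki67 and Stmn1, held 72 of 1739 control, 10 of 1555 infected and 4 of 1080 PLX5622 microglia-like cells. The neutrophil attracting chemokine Cxcl2 was at 0.201 times the control level (0.182 to 0.221), within an inflammatory cytokine and NF-kB list where 2 of 27 members were lower and none higher (median -0.11, percentile 0.195). Immediate early and dissociation genes, which respond within minutes to handling and stimuli, had a median of -0.24 (-0.30 to -0.16, percentile 0) with 3 of 37 members lower, among them Gadd45b and Ier3 at 0.648 and 0.657 times. With only the clusters low in these genes counted, their median turned to 0.043. The RPE transcripts Ttr and Ptgds were at 0.423 and 0.523 times the control level, and Ttr turned to a log2 ratio of 0.042 with all kept cells.

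The identity genes of microglia stayed close to the control level. Members of the homeostatic list, P2ry12, Tmem119 and Csf1r among them, also served to name the class. In all comparisons, cells that lost them would fall outside the class, so a fall could be missed. P2ry12, a purine receptor, was at 1.10 times (1.09 to 1.12), Tmem119 at 1.24 times, and Csf1r, the survival receptor, at 0.908 times. The homeostatic list had 1 of 27 members lower (Fcrls, 0.421 times) and none higher, with a median of 0.07 (-0.07 to 0.15). P2ry12 gave a UMI in 79.1% of thinned control and 81.7% of thinned infected microglia-like cells, and in 0.976% and 1.32% of RPE-like cells; unthinned microglia-like shares were 95.9% and 97.9%. Disease-associated genes, seen in microglia around plaques and injury, had a median of 0.03 with 1 of 29 members lower (Ank, 0.607 times), and Apoe was at 0.814 times the control level. Fabp5, Spp1 and Cst7 of that list were among the leading genes of unnamed cluster 11, which lay outside the class. Adding clusters 11 and 12 moved no list median outside its interval. Phagocytosis and lysosome genes had a median of 0.03 with 1 of 37 higher, the protease gene Ctsc (1.71 times). Lipid and cholesterol genes had a median of 0.12 with 1 of 20 higher and 1 lower, the desaturase gene Scd2 (0.647 times). Glycolysis and hypoxia genes had a median of 0.08 (-0.021 in thinned cells) with P4ha1 at 1.70 and the glucose transporter Slc2a3 at 0.509 times. Oxidative phosphorylation genes had a median of -0.13 (-0.18 to -0.09, percentile 0) with 2 of 69 lower, Ndufb4 and Ndufa3 at 0.618 and 0.657 times. CSF1R and TGF-beta signalling (25 members, median 0.06), angiogenesis (16 members, -0.11), unfolded protein and oxidative stress (23 members, -0.05) and senescence (19 members, -0.14) had no member 1.5 times away. The signature of macrophage-derived cells had a median of 0.02 with 4 of 16 higher, of which H2-Aa, H2-Eb1 and Cd74 also belong to the class II list and the remaining one was Ifitm3, at 1.61 times.

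Several of these genes lie close together on mouse chromosome 17 (GRCm38, GENCODE vM21). H2-Eb1 (ENSMUSG00000060586) spans 34305867 to 34316674 on the plus strand, H2-Aa (ENSMUSG00000036594) 34282744 to 34287823 on the minus strand, and C4b (ENSMUSG00000073418) 34728380 to 34743882 on the minus strand. Cd74 (ENSMUSG00000024610) and Iigp1 (ENSMUSG00000054072) lie on chromosome 18, at 60803848 to 60812652 and 60376027 to 60392634. Cxcl13 (ENSMUSG00000023078) and Cxcl9 (ENSMUSG00000029417) lie on chromosome 5, at 95956951 to 95961068 and 92321347 to 92328079. P2ry12 (ENSMUSG00000036353) spans 59216272 to 59262871 on chromosome 3. All are annotated as protein-coding.

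**Figure D2:**
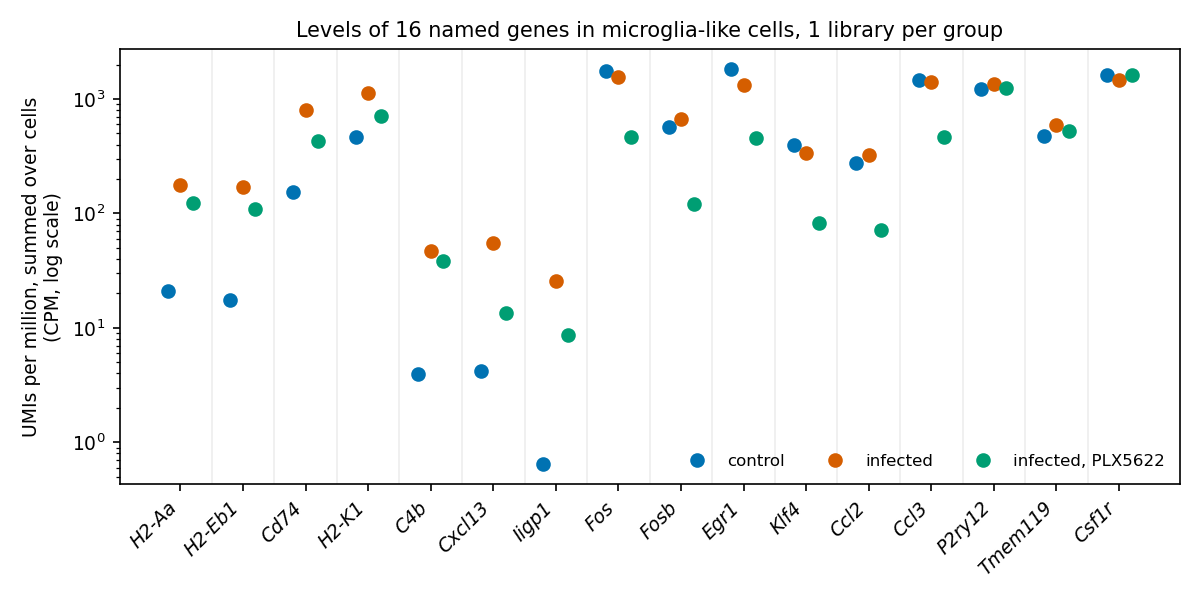
Level in microglia-like cells, in CPM on a log axis, of 16 genes in the control, infected and PLX5622 libraries, 1 point per library without intervals. H2-Aa stood at 21.0, 178 and 123 CPM, and Fosb at 564, 666 and 121 CPM.

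The second comparison, PLX5622 against infected, asks whether replacing the microglia alters the state that infection left. No uninfected group was given PLX5622. An effect of depletion and regrowth by themselves therefore cannot be told apart from a change of the infection state, here or against control. Activation genes that respond within minutes were far lower in the PLX5622 library. Fosb and Fos, parts of the AP-1 transcription factor, stood at 121 and 465 CPM against 666 and 1551 CPM, ratios of 0.182 (0.170 to 0.194) and 0.300 (0.290 to 0.311). The chemokine Ccl2, which draws monocytes, was at 71.0 against 323 CPM (0.220, 0.201 to 0.240), and Ccl3 at 0.334 times the infected level. The antigen presentation genes H2-Aa and Cd74 were at 0.689 (0.641 to 0.740) and 0.528 times (0.509 to 0.548). Cluster 1 held 52.5% of PLX5622 microglia-like cells, with 13.7% in cluster 9 and 13.4% in cluster 4. Their median depth was 5599 UMIs against 10062.

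The immediate early and dissociation list had 29 of 37 members at least 1.5 times lower and none higher (median -1.04, -1.21 to -0.80, percentile 0). It included Egr1 (0.346 times), Klf4 (0.248 times) and the phosphatase Dusp1 (0.266 times). Klf2, of the CSF1R and TGF-beta signalling list, stood at 0.254 times. RPE-like cells, measured beside them, had a median of -0.26 (-0.64 to -0.15) with 11 of 31 members lower. Inflammatory cytokine and NF-kB genes had 12 of 28 members lower and 2 higher (median -0.56, -0.70 to -0.32, percentile 0). Lower ones included Nfkbia, the NF-kB inhibitor, at 0.515 times, while Cxcl2 stood at 1.90 times the infected level. Unfolded protein and oxidative stress genes had 10 of 22 members lower and none higher (median -0.52, -0.92 to -0.22, percentile 0). Srxn1 and Gclc, which counter oxidants, were at 0.175 and 0.399 times, Atf4, a stress transcription factor, at 0.443 times, and Hmox1, which breaks down haem, at 0.482 times.

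Of the 12 MHC class II members 4 were lower and none higher (median -0.38, -0.77 to 0.03, percentile 0.070). H2-DMb1 was at 0.410, H2-Ab1 at 0.567 and H2-Eb1 at 0.637 times the infected level. Here 112 of 1080 PLX5622 cells had 10 or more class II UMIs and held 74.2% of them, a limit that depends on depth, with means of 7042 UMIs per cell against 15190 in infected cells. H2-Aa gave a UMI in 8.43% of thinned PLX5622 cells against 11.8% of infected ones, and in 2.90% against 0.661% of RPE-like cells. Unthinned shares were 16.5% against 30.1% of microglia-like and 4.25% against 1.42% of RPE-like cells, whose median depths were 2394 and 2894 UMIs. The macrophage markers Mrc1 and Pf4 stood at 9.99 and 20.2 CPM in PLX5622 microglia-like cells against 3.77 and 5.08 CPM. MHC class I genes had 4 of 24 members lower and none higher (median -0.34, -0.47 to -0.10, percentile 0), with H2-Q6 at 0.506, H2-Q4 at 0.540 and H2-K1 at 0.638 times. Interferon gamma genes had 3 of 21 lower and none higher (median -0.34, -0.44 to -0.12, percentile 0.040). Iigp1 was at 0.339 and Irgm2, another GTPase, at 0.472 times. Cxcl13 was at 0.242 times the infected level (0.196 to 0.296). Type I interferon genes had 1 of 28 higher, the RNA sensor Rigi (1.62 times), and 1 lower, Ifi207 (0.478 times), with a median of 0.10 (-0.04 to 0.28). C4b was at 0.809 times in a complement list with a median of -0.15 and 1 of 10 lower (C3ar1, 0.602 times).

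Higher in PLX5622 cells were Mctp1, a membrane protein with calcium-binding domains (2.70 times, 2.55 to 2.86), Tafa1, a secreted chemokine-like protein (2.15 times), Hes1, a Notch target (1.86 times), and Slc2a3 (2.53 times). Cdkn2a, a brake on the cell cycle, was at 32.6 against 11.2 CPM (2.91 times, 2.43 to 3.47), while Cdkn1a, another such brake, was at 0.433 times. Their senescence list had 2 of 19 members higher and 4 lower (median -0.12). The RPE transcripts Ttr and Ptgds were at 2.66 and 2.29 times the infected level. P2ry12, Tmem119 and Csf1r stood at 0.922, 0.886 and 1.09 times, and the homeostatic list had 1 of 26 lower and none higher with a median of -0.05. CSF1R and TGF-beta signalling had 6 of 25 lower (median -0.03), including Cebpa, a myeloid transcription factor, at 0.626 times, and Tgfbr1, a TGF-beta receptor, stood at 1.49 times. Disease-associated genes had 2 of 29 lower (median -0.10), among them Spp1 (osteopontin) at 0.475 times, and Apoe was at 1.30 times. The angiogenesis list had 3 of 16 lower (median -0.13), with the urokinase receptor gene Plaur at 0.404 times. Phagocytosis genes had 2 of 37 lower (median -0.07), with Ctsc at 0.527 times. Lipid genes had 2 of 20 higher (median -0.11), with Apoc1 at 1.65 times. Glycolysis genes had 1 of 25 higher and 1 lower (median -0.06), the latter being the glucose transporter Slc2a1 (0.516 times). Oxidative phosphorylation genes had 2 of 69 higher (median 0.14, 0.04 to 0.19), with Ndufa3 at 1.81 times, and the median turned to -0.0033 at clustering resolution 0.5 and to -0.16 with only clusters low in immediate early genes. The proliferation list, reduced to 5 measured members, had 2 lower (median -0.34), and the signature of macrophage-derived cells 3 of 16 lower (median -0.07). The median of that signature lay between -0.22 and 0.96 in 17 alternatives and kept its sign in 7.

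The position of the class II genes depended on the cells counted. With all kept cells the log2 ratios of Cd74, H2-Ab1, H2-Eb1 and H2-DMb1 to the infected level were 1.12, 1.08, 1.46 and 0.41 (list median 0.11), and with macrophage-like cells added 1.39, 1.39, 1.79 and 0.66 (list median 0.41). With all kept cells H2-Aa stood at 1.69, with macrophage-like cells added at 2.02, with a stricter cell filter at 0.92 and with all barcodes at 0.14, each above the infected level. The stricter filter also put H2-Ab1 at 0.17 and H2-Eb1 at 0.60. Ifi207 stood above the infected level with all kept cells, with macrophage-like cells added and with libraries clustered on their own, at 0.05, 0.34 and 0.48, and Csf1r below it with all kept cells, at -0.08. With libraries clustered on their own Srxn1, Hmox1 and Plaur stood above the infected level, at 2.49, 0.62 and 0.89, and with only clusters low in immediate early genes Cxcl2, Apoe and Apoc1 stood below it, at -1.14, -0.18 and -0.20.

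The third comparison, PLX5622 against control, asks how far regrown microglia resembled those of uninfected mice. Type I interferon genes stood above control and immediate early genes below it. Ifit2 and C4b were at 2.91 and 9.69 times the control level, H2-Aa at 5.84 times (5.23 to 6.53) and Cd74 at 2.74 times (2.61 to 2.88). Cxcl9 stood at 23.5 CPM, at least 183-fold above the control limit. Fos and Egr1 were at 0.264 and 0.251 times. P2ry12 was at 1.02 times (0.994 to 1.04) and Csf1r at 0.990 times (0.970 to 1.01), differences not detectable at this depth. Both genes also served to name the class.

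The type I interferon list had 14 of 27 members at least 1.5 times higher and none lower (median 0.61, 0.41 to 0.81, percentile 100), with Sp100 at 2.78 and Parp14 at 2.12 times. Interferon gamma genes had 3 of 19 higher and 2 lower (median 0.04), with Gm4951 at 6.52 and Socs3, a brake on cytokine signals, at 0.386 times. The MHC class I list had 4 of 23 higher (median 0.28, 0.20 to 0.48, percentile 93.2), with Nlrc5 at 2.89 times, and B2m stood at 1.22 times. The class II list had 5 of 12 higher (median 0.29, -0.04 to 1.19), with H2-Eb1 at 6.18 times. Median-ratio scaling, under which H2-DMb1 (20.9 CPM here) no longer reached 20 CPM, put the class II median at -0.059. Mrc1 and Pf4 stood at 9.99 and 20.2 CPM beside 5.41 and 4.98 CPM in control microglia-like cells. The highest ratio among genes with at least 50 CPM belonged to Tafa1, at 10.4 times (8.96 to 12.05).

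Immediate early genes had 33 of 37 members lower (median -1.19, -1.40 to -1.06, percentile 0), with Klf4 at 0.209 and Fosb at 0.215 times. Inflammatory genes had 18 of 28 lower and 1 higher (median -0.68, -0.89 to -0.53, percentile 0), with Ccl2 at 0.258, Ccl3 at 0.320 and Nfkbia at 0.344 times. Stress genes had 11 of 22 lower (median -0.65, -0.90 to -0.34, percentile 0), with the chaperone Hspa5 at 0.381 and the metallothionein Mt1 at 0.478 times, which turned to a log2 ratio of 0.52 with all kept cells. Proliferation genes had 9 of 10 lower (median -1.47, -3.60 to -0.79, percentile 0), with Mki67 at 0.0473 times. Senescence genes had 2 of 21 higher and 9 lower (median -0.22). Homeostatic genes had 2 of 27 higher and 3 lower (median 0.03), with Tgfbr1 at 1.95 and Fcrls at 0.461 times. The other medians lay between -0.16 and 0.05. They were -0.16 for disease-associated genes (1 of 28 higher, 1 lower), -0.15 for angiogenesis (2 of 15 lower), -0.10 for phagocytosis (1 of 37 higher, Mitf, 1.70 times), -0.08 for complement (1 of 10 higher, 1 lower) and -0.04 for oxidative phosphorylation (69 members). The signature of macrophage-derived cells stood at -0.04 (4 of 16 higher), CSF1R and TGF-beta signalling at -0.01 (1 of 25 higher, 4 lower), glycolysis at 0.01 (1 of 24 higher) and lipid genes at 0.05 (2 of 19 higher).

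To choose genes in other infected cells than those that give their values, infected cells were split at random; the control cells served both for the choice and for the values against control. Of the genes chosen in 777 infected cells, 44 were higher than in control, and in the other 778 cells their median log2 ratio to control was 0.87. In PLX5622 cells their median lay at -0.41 (-0.59 to -0.26) against those other infected cells and at 0.60 against control. Of these genes 75% (33 of 44) were below the infected level, against 45.4% of all 3469 genes. Both parts come from the same infected library, so its library-level deviations enter the choice and the values alike. Part of the fall below the infected level may come from that choice. The 29 genes lower in infected cells had a median of -0.73 against control and of -0.20 (-0.41 to 0.41) between PLX5622 and infected cells, and stood at -0.93 between PLX5622 and control.

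**Figure D3:**
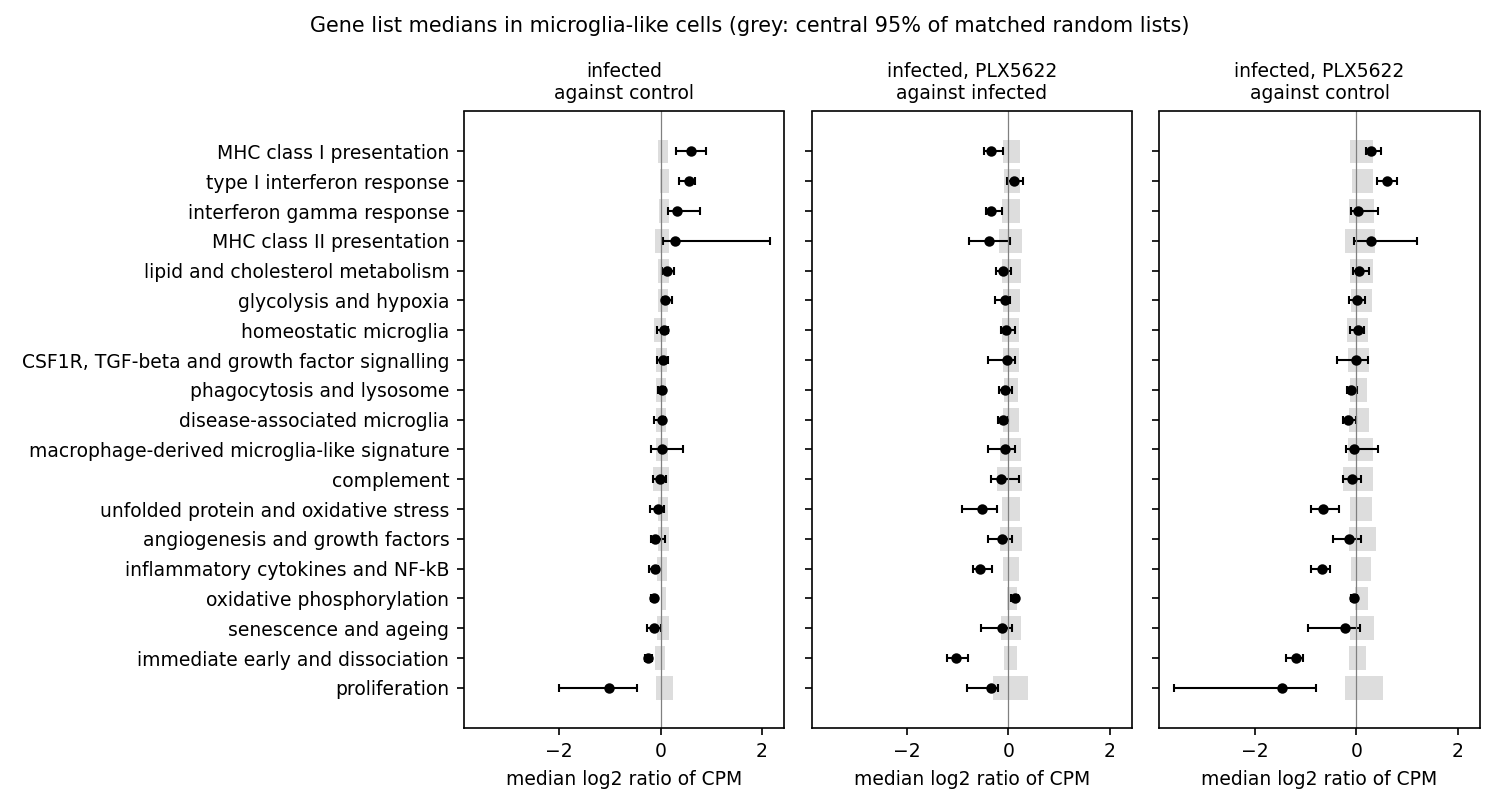
Median log2 ratio (horizontal axis) of 19 gene lists in microglia-like cells for the 3 comparisons, as points with resampling intervals, over grey bars for the central 95% of matched random lists. For PLX5622 against infected the immediate early list lay at -1.04, and for infected against control the MHC class I list at 0.60.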

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

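All tests in this part except that of the mix of microglia-like clusters were chosen after the result was seen, as was the use of the antibody tags. The matrices hold counts of 14 antibody tags that no comparison of gene expression uses, and 3 of their ratios in microglia-like cells were at 1.5 times the control level or more. The MHCII tag per isotype tag was at 1.517 times the control level in infected microglia-like cells (a median of 0.172 against 0.114), and at 0.825 times in RPE-like and 1.17 times in neutrophil-like cells, while barcodes under 100 genes, with tags summed, gave 0.317 in the infected and 0.206 in the control library. The P2RY12 tag was at 1.617 times in infected microglia-like cells (2.18 against 1.35; 0.790 against 0.569, under 1.5 times, with tags summed over cells), at 1.17 times in RPE-like cells and at 1.57 times in neutrophil-like cells, which are not known to carry the protein. The MHCII tag was at 7.696 times the control level in PLX5622 microglia-like cells (0.875 against 0.114). These differences were not tested, since each group had 1 library.

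Immediate early genes such as Fos, Fosb and Egr1 were lower in microglia-like cells of the PLX5622 library than in the infected library (median -1.04), and these genes also respond to tissue dissociation. If handling differed between the libraries, other cells should shift the same way. RPE-like cells stood at -0.2646 (-0.64 to -0.15) and macrophage-like cells at -0.71 (-0.82 to -0.62). A part shared by all cells of the library, or free microglial RNA in their droplets, could give this. Little such RNA was seen in RPE-like cells, with P2ry12 at 8.47 CPM (infected) and 17.4 CPM (PLX5622) beside 1361 and 1255 CPM in microglia-like cells. Csf1r stood at 54.6 and 82.4 CPM beside 1474 and 1608 CPM. Of the homeostatic list 5 of 11 members were higher in PLX5622 than in infected RPE-like cells and none lower. With each microglia-like cluster given its share among infected cells the median was -0.4583 (-0.59 to -0.03), so the mix of clusters may carry part of the difference, while with only the clusters low in these genes it was -0.93. The mix of clusters and an effect on all cells cannot be told apart, because the interval spans the bound set for it, the clusters themselves separate by these genes, and the mix also differs among the low ones. A response of regrown microglia to PLX5622 treatment remains open and untested, as treatment and library coincide.

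MHC class II RNA stood above control in microglia-like cells of both infected libraries, and macrophage-like cells, rich in H2-Aa and Cd74, could have supplied it. In the infected library macrophage markers implied an added share of macrophage RNA of -0.3434% (-1.52 to 2.25%), while the class II genes would need 9.42%. This argues against free RNA with the marker content of the macrophage-like class. Whole cells are less settled, as 475 of 1555 cells, with 10 or more class II UMIs each, held 91.1% of these UMIs. The same markers served to name the classes, so cells rich in them had already been set apart. Clustered on its own, this library gave a macrophage-like share of 6.28% instead of 3.78%, so macrophages among the microglia-like cells are not excluded. The 5 markers ranged singly from -1.76% (Dab2) to 2.79% (Ccl8), and class II-rich cells that lack them were not tested. In the PLX5622 library the markers implied 2.7138% (0.84 to 8.15%) and the class II genes 3.18%, so RNA or cells of macrophages may account for the class II RNA there. The MHCII tag of that library was at 6.1111 times the control level in RPE-like cells and 7.70 times in microglia-like cells, which is consistent with antibody bound or carried unspecifically as a source of the tag, although tags summed over barcodes were less far apart elsewhere, at 0.727 against 0.520 in neutrophil-like cells (12 and 79 cells; medians 5.43 times) and 0.587 against 0.206 in barcodes under 100 genes. A lasting effect of infection on class II genes of microglia in the infected library stays a hypothesis, and an effect of PLX5622 treatment is open and untested.

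Macrophage-like cells held 13.05% of kept cells in the PLX5622 library and 3.78% in the infected one. They also carried the microglial gene P2ry12, at 749 and 892 CPM. A lower yield of microglia alone would leave macrophage-like cells per RPE-like cell alike, but this ratio was 3.1901 times the infected one (2.55 to 3.99). Per RPE-like cell, neutrophil-like cells were at 0.305 times and rods at 2.49 times (1.67 to 3.70, 88 against 36 cells). RPE-like cells are not expected to pass the gate, so they are no fixed reference. Against rods the rise of macrophage-like cells would be far smaller, so the result depends on the reference and does not settle how recovery differed. Droplets joining a macrophage and a retinal cell are unlikely to be the whole source, as 11.7419% (10.58 to 12.98%) remained without cells holding over 1% of retinal marker UMIs, and 9.59% (8.53 to 10.7%) without cells whose own-library cluster was RPE-like or led by retinal genes. Over all kept cells, with no clusters used, 7 macrophage markers had a median ratio of 3.3306 (1.73 to 5.26), among them Mrc1 at 6.61. The other markers of the class were not counted. F13a1, which gave the median, stood at 6.53 CPM in the infected and 21.7 CPM in the PLX5622 library. Mrc1 and Ccl8 were also under 20 CPM in the infected library only, and counting such markers favours high ratios. Pf4, Stab1, Dab2 and Ms4a7, at 20 CPM or more in both libraries, ranged from 1.67 (Stab1) to 5.09 (Pf4). Marker RNA was thus higher without any naming of clusters. How much of the difference in share came from naming stays open, as naming within each library put the share at 1.73%. A difference in how choroid or vessels were carried through dissection and sorting was not tested, and PLX5622 treatment is open and untested.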

How the results depend on the processing

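Values under settings with added clusters 11 and 12, without cluster 9, with only clusters low in immediate early genes, with swapped parts of the infected cells, and expression values at resolutions 0.5 and 2 or with doublets kept were chosen after seeing the data. Of the list medians 890 of 969 alternative values stayed within the interval of the reported value, 75 moved outside it, and 4 turned against an interval that excluded 0. For infected against control the type I interferon median lay between 0.29 and 0.65 in all 17 alternatives, the MHC class I median between 0.45 and 0.66, the class II median between 0.18 and 1.003 and the interferon gamma median between 0.25 and 1.04. For PLX5622 against infected the immediate early median lay between -1.10 and -0.73, the inflammatory median between -0.63 and -0.15 and the stress median between -0.58 and -0.10. The MHC class II median of that comparison lay between -0.54 and 0.41 and kept its sign in 14 of 17 alternatives, and that of PLX5622 against control between -0.059 and 0.997, with its sign kept in 15. Medians close to 0 turned more often: the macrophage signature kept its sign in 5, 7 and 7 of 17 alternatives for infected against control, PLX5622 against infected and PLX5622 against control. The total without mitochondrial and ribosomal protein genes moved no list median outside its interval, and neither did expression values at resolution 2 or with clusters 11 and 12 added. Of the named gene ratios 2589 of 3930 alternative values stayed in the interval, 1281 moved outside it, and 60 turned against an interval that excluded 0. Of the class shares 118 of 192 stayed in their intervals, and all 21 shares of cells with a UMI moved without thinning, since depth sets them. Swapping the parts of the infected cells gave -0.40 for 49 genes higher in infected cells and -0.11 for 24 lower ones, both within their intervals. No paired analysis was possible because each group had 1 library. No NK cell cluster was named at resolution 0.5 or with libraries clustered on their own, so these gave no NK share.

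The following gene values are log2 ratios that turned, and the following list values are log2 medians that left their interval. The cause was not tested. All barcodes gave microglia-like shares of 24.6%, 24.8% and 13.7% (control, infected, PLX5622), macrophage-like shares of 0.944%, 1.42% and 3.77% and RPE-like shares of 20.7%, 21.7% and 22.6%. Their medians of infected against control were -0.27 (angiogenesis), 0.020 (glycolysis), -0.29 (inflammatory) and 0.32 (type I interferon). Interferon gamma stood at -0.079 for PLX5622 against infected, where H2-Aa was at 0.14. Srxn1 was at -0.057 for infected against control. The stricter filter gave microglia-like shares of 56.2%, 63.2% and 52.3% and RPE-like shares of 23.8%, 22.5% and 24.4%. Macrophage-like shares were 3.88% (control) and 11.2% (PLX5622). Oxidative phosphorylation was at -0.067 for infected against control. For PLX5622 against infected, MHC class II was at 0.066, the macrophage signature at 0.30, H2-Aa at 0.92, H2-Ab1 at 0.17 and H2-Eb1 at 0.60.

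All kept cells gave -0.18 (angiogenesis), -0.23 (inflammatory) and -0.056 (oxidative phosphorylation) for infected against control, with Srxn1 at -0.17 and Ttr at 0.042. PLX5622 against infected gave 0.11 (MHC class II), 0.16 (angiogenesis), -0.32 (homeostatic), -0.73 (immediate early), -0.27 (inflammatory), 0.48 (macrophage signature) and 0.35 (oxidative phosphorylation). Its genes were Cd74 at 1.12, Csf1r at -0.075, H2-Aa at 1.69, H2-Ab1 at 1.08, H2-DMb1 at 0.41, H2-Eb1 at 1.46, Ifi207 at 0.049 and Slc16a1 at 0.065. PLX5622 against control gave 0.16 (angiogenesis), -0.21 (homeostatic), -0.998 (immediate early), -0.44 (inflammatory), 0.25 (oxidative phosphorylation) and -0.32 (stress). Atp5g3 was there at 0.14, Cxcl2 at 0.13, Cycs at 0.0004, Mt1 at 0.52, Mt2 at 0.65, Slc2a1 at 0.056 and Tmem119 at -0.075.

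Microglia-like and macrophage-like cells together gave, for PLX5622 against infected, 0.41 (MHC class II), -0.21 (homeostatic), -0.15 (inflammatory), 0.96 (macrophage signature) and 0.34 (type I interferon). Cd74 was at 1.39, H2-Aa at 2.02, H2-Ab1 at 1.39, H2-DMb1 at 0.66, H2-Eb1 at 1.79 and Ifi207 at 0.34. Against control they gave -0.15 (homeostatic), -0.35 (inflammatory), 0.56 (macrophage signature), 0.031 (oxidative phosphorylation), 0.85 (type I interferon) and -0.27 (stress). Cxcl2 was at 0.56, Mt2 at 0.44 and Tmem119 at -0.022.

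Libraries clustered on their own gave a microglia-like share of 41.97% (infected) and macrophage-like shares of 6.28% (infected) and 1.73% (PLX5622). Infected against control gave -0.24 (angiogenesis), -0.31 (immediate early), -0.39 (inflammatory), -0.080 (oxidative phosphorylation) and -0.33 (stress), with Hbegf at -0.30 and Srxn1 at -2.95. In PLX5622 against infected, medians were 0.14 (angiogenesis), -0.16 (homeostatic), -0.29 (inflammatory), 0.042 (oxidative phosphorylation) and -0.10 (stress). Cd44 was at 1.405, Hmox1 at 0.62, Ifi207 at 0.48, Lgals3 at 0.27, Plaur at 0.89 and Srxn1 at 2.49, and against control Gpnmb was at -0.10.

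Resolution 0.5 gave microglia-like shares of 35.1%, 42.6% and 31.3%. Oxidative phosphorylation was then at -0.051 for infected against control, with Srxn1 at -0.63. In PLX5622 against infected it turned to -0.0033, with Cd44 at 0.073. Resolution 2 gave macrophage-like shares of 2.84%, 2.73% and 7.86%. Thinned cells gave -0.021 (glycolysis, turned), -0.069 (immediate early) and -0.27 (oxidative phosphorylation) for infected against control. Against control, PLX5622 cells then gave -0.17 (oxidative phosphorylation), with Apoe at -0.12. The mean of per-cell CPM gave -0.085 (immediate early) and -0.24 (oxidative phosphorylation) for infected against control and -0.15 (proliferation) for PLX5622 against infected. For PLX5622 against control it gave -0.12 (oxidative phosphorylation), with Apoe at -0.048. Median-ratio scaling gave, for the same comparison, 0.18 (MHC class I), -0.059 (MHC class II), -0.15 (oxidative phosphorylation) and -0.20 (phagocytosis), with Apoe at -0.019. Members with any count gave 0.12 (complement) and 1.04 (interferon gamma) for infected against control. They gave 0.15 (macrophage signature) for PLX5622 against infected and 0.44 (interferon gamma) for PLX5622 against control. Members at 50 CPM gave proliferation medians of -0.46 (infected against control) and -0.77 (PLX5622 against control).

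Clusters low in immediate early genes gave, for infected against control, 0.043 (immediate early, turned) and 0.29 (type I interferon). Cebpb was at 0.043, Hbegf at -0.15, Hspa1b at 0.28, Nfkbiz at 0.21 and Srxn1 at -1.01. In PLX5622 against infected they gave -0.32 (disease-associated), -0.29 (glycolysis), -0.16 (oxidative phosphorylation, turned) and -1.46 (proliferation). Apoc1 was at -0.20, Apoe at -0.18, Cd44 at 0.14 and Cxcl2 at -1.14. In PLX5622 against control they gave 0.12 (MHC class I), -0.38 (disease-associated), -0.91 (immediate early), -0.22 (macrophage signature), -0.36 (oxidative phosphorylation) and -0.20 (phagocytosis). Apoc1 was at -0.062, Apoe at -0.42, Gpnmb at -0.29, Ifitm3 at -0.20 and Slc2a1 at 0.14. Adding clusters 11 and 12 put Srxn1 at -0.040 for infected against control. Leaving out cluster 9 put oxidative phosphorylation at -0.070 in that comparison, and kept doublets put it at 0.19 for PLX5622 against infected.

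Depth limits the PLX5622 library most, with 7605540 UMIs over its microglia-like cells against 23616184 in the infected library. The share of cells with an H2-Aa UMI was 8.43% thinned and 16.5% unthinned there. Division genes were near the limit of counting, with Mki67 at 1.31 CPM and Top2a at 2.63 CPM, and 5 of the 10 proliferation genes measured in the other comparisons were under 20 CPM in both the infected and the PLX5622 library.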

Other observations

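No test was run in this part, and its values for other cell classes and tags were chosen after seeing the data. Interferon genes were also higher in macrophage-like cells of the infected library (118 cells against 181 in the control). The type I interferon list had 16 of 34 members at least 1.5 times higher and 1 lower (median log2 ratio 0.52, interval 0.35 to 0.73), with Irf7, the amplifier of interferon production, at 50.2 against 15.2 CPM and Isg15 at 50.6 against 19.1 CPM. MHC class I genes had 13 of 22 higher and none lower (median 0.64, 0.41 to 0.89), with H2-K1 at 1255 against 601 CPM. Interferon gamma genes had 8 of 21 higher (median 0.20), with Cxcl9 at 132 against 0.324 CPM, Gbp4 at 22.9 against 3.57 CPM and Iigp1 at 34.2 against 7.13 CPM. MHC class II genes, already high in these cells, had 1 of 14 higher (median 0.21), with H2-Aa at 2318 against 1860 CPM. In the PLX5622 library (370 cells, most of them in unnamed clusters when that library was clustered on its own) H2-Aa stood at 3579 CPM, Ciita, the transactivator of class II genes, at 51.8 against 24.2 CPM in the infected library, and the scavenger receptor Mrc1 at 392 against 224 CPM. Immediate early genes there had 26 of 39 members lower than in the infected library and none higher (median -0.71), with Fosb at 294 against 588 CPM.

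RPE-like cells carried interferon genes in the infected library too, although 7 members only were measured. Of these 5 were at least 1.5 times higher than in the control and none lower (median 1.72, 0.24 to 2.64). Ifitm3, which blocks virus entry, was at 12.9, 74.1 and 47.0 CPM in control, infected and PLX5622 RPE-like cells, and Bst2, which tethers virus particles, at 86.5, 295 and 190 CPM. Isg15 was at 0.605 CPM in the control and 24.5 CPM in the infected library. MHC class I genes had 2 of 11 higher (median 0.26), with H2-K1 at 67.0, 146 and 113 CPM and B2m at 377, 544 and 479 CPM. H2-K1 stood at 469, 1120 and 714 CPM in microglia-like cells, and free RNA was not subtracted from RPE-like counts. Socs3, an immediate early gene in the list used here, was at 83.5 CPM in infected and 6.20 CPM in PLX5622 RPE-like cells.

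A group of genes outside the fixed lists took the same order over the libraries in 3 classes. Cmss1 stood at 218, 585 and 908 CPM in control, infected and PLX5622 microglia-like cells, at 183, 435 and 601 CPM in macrophage-like cells and at 487, 1972 and 2130 CPM in RPE-like cells. Cdk8 stood at 122, 260 and 427 CPM, at 106, 202 and 280 CPM and at 163, 576 and 681 CPM in these classes. Lars2 stood at 56.1, 118 and 187 CPM, at 49.3, 98.2 and 158 CPM and at 149, 399 and 491 CPM. Whether this order is technical was not tested. The RPE transcripts Ttr and Ptgds stood at 271, 445 and 1721 CPM and at 329, 697 and 1861 CPM in macrophage-like cells. The sex-linked transcripts Xist, at 372, 522 and 375 CPM in microglia-like cells, and Ddx3y, at 96.3, 55.8 and 44.0 CPM, were both present in each pool. Ddx3y fell in the same order in macrophage-like cells (95.6, 63.6 and 51.8 CPM) and RPE-like cells (63.3, 38.1 and 32.8 CPM). Xist did not rise in step, at 598, 626 and 373 CPM and at 195, 152 and 188 CPM there. Uty, also Y-linked, stood at 88.1, 59.2 and 86.6 CPM in microglia-like cells. The mix of sexes may thus differ between the pools, which was not tested.

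Surface tags, as medians per isotype tag, gave further values. In macrophage-like cells the MHCII tag stood at 1.18, 8.10 and 5.30 in control, infected and PLX5622 cells, with control quartiles of 0.104 and 12.7. With tags summed over cells the values were 2.64, 4.89 and 4.08. CD86, a costimulatory receptor, stood at 0.484, 0.676 and 0.20 in microglia-like cells (summed 0.185, 0.224 and 0.138). The same order was seen in macrophage-like cells (0.331, 0.566 and 0.271) and neutrophil-like cells (0.342, 0.392 and 0.197), so it was not particular to microglia-like cells. RPE-like cells went the other way (0.143, 0.125 and 0.172). For F4-80, a macrophage antigen, and CD64, an Fc receptor, the order depended on the measure. In microglia-like cells F4-80 stood at 1.28, 1.85 and 1.13 as medians and at 0.769, 0.894 and 0.941 summed. CD64 stood at 2.40, 2.46 and 1.77 as medians and at 1.27, 1.25 and 1.46 summed in the same cells. The P2RY12 tag stood at 0.829 in PLX5622 microglia-like cells against 2.18 in infected ones (summed 0.555 against 0.790), and at 0.396 against 0.902 in neutrophil-like cells (12 and 40 cells), which are not known to carry the protein. In microglia-like cells P2ry12 RNA stood at 0.922 times the infected level. Neutrophil-like cells carried the Ly6G tag at 48.7, 27.3 and 24.6, against 0.115 in control microglia-like cells.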
